A study of Homo sapiens with 8 samples.

How the data were processed

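Total RNA from 2 human gastric cancer cell lines, MKN7 and TMK1, was measured on 8 single-colour Affymetrix expression arrays, 1 array for each combination of line and transduction. Per the labels' protocols, a retroviral vector carried the homeobox factor CDX1, the related factor CDX2, or the puromycin resistance gene alone. Selection with 1.0 µg/ml puromycin started 72 hours after infection, and RNA was taken on day 7, when selection was complete. Uninfected cells of each line were the other control, and no day is given for them in the sources used here. Per the labels' protocols, RNA was copied into cDNA from an oligo(dT) primer and transcribed in vitro into biotin-labelled cRNA. Priming from the poly(A) tail makes signal fall towards the 5' end of a transcript as RNA breaks, which is why 3' to 5' signal ratios are given with the results.

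The deposited table holds 1 intensity value per probe set and array on a linear scale, for 54675 probe sets. MAS5 was used, per the submitters' processing notes, and its version is not given in the sources used here. The deposited values had a 2% trimmed mean of 100.01 to 100.02 on every array, as found from the values themselves. Array medians lay between 8.0 and 11.9, and the maxima between 8414.2 and 13706.7. No detection calls were used, so the deposited table does not mark which probe sets were above background. A signal under its array's median was treated as not clearly above background. For genes with such signals the change was also computed with every signal raised to at least its array's median. MAS5 can give unstable ratios at low signal, and that limits the precision of changes in dim genes. The number of arrays limits the precision of all values.

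Gene names came from the platform annotation of the probe sets. Of the probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 had none in the table used. No symbol needed an update against a current gene table. Probe sets with several symbols or none stayed out of the tests by gene, as did the 62 Affymetrix control probe sets. The probe set with the highest mean signal stood for each of 19775 genes. A gene was tested if at least 2 of the 8 arrays exceeded their own array's median, which left 14220 genes. Values were analysed as log2(signal + 2), where 2 is the 20th percentile of the table. The offset shrinks the folds of dim genes. It lies under the median of every array, so signals near background can still give large folds. Members of a fixed list without a named probe set were not analysed here.

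Each gene was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. CDX1 and CDX2 together were set against both controls with cell line as a block, with 5 residual degrees of freedom. This fit took CDX1 and CDX2 as repeats within a line, and uninfected and vector likewise. CDX1, CDX2, vector and uninfected were also fitted as separate levels, again with the line as a block and 3 residual degrees of freedom. The test of TMK1 against MKN7 used transduction as the block. A line by CDX interaction, with 4 residual degrees of freedom, tested whether the response differed between the lines. It took CDX1 and CDX2 as repeats within a line, and uninfected and vector likewise, so its spread includes the differences between them. Cell lines were the only repeats of a transduction, and arrays of one line paired naturally across transductions. Arrays of the same line correlated across genes at r = 0.935 to 0.978, against 0.756 to 0.807 for arrays of different lines. On any 2 arrays at most 845 probe sets had the same value, so none is a copy of another. The labels name no separate cultures, so the p-values measure only the spread between these 8 arrays and 2 lines.

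The 29 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks only whether a list's genes move one way on balance, were the alternatives. The median of each list on each CDX array was also set among 10000 random lists matched on mean expression. Calls by gene were counted over all tested genes and adjusted over the list alone. Within one line, each CDX array was set against both control arrays at 2-fold with no test. To see whether CDX1 and CDX2 responses were alike despite shared control arrays, correlations were recomputed with the controls split. They were also set beside 20 simulations of unchanged groups. The 3' to 5' ratios of the control probe sets for GAPDH and ACTB were compared by an exact two-sided permutation test over the 36 exchanges of arrays within lines.

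The rule for named genes took the 12 genes per direction with the largest smaller change of the lines among those past the threshold. For the comparison of the lines and the interaction, the fitted change ranked the genes. Where fewer than 5 genes passed in a direction, the 5 largest were named as values that did not pass. Up to 4 members of each list with the lowest p were named, and 5 genes per direction within a line. The grouping, tests, gene lists, naming rule and alternative settings were fixed before the data were examined. These settings were quantile normalization, centring on the median, other offsets, filters and probe set rules, no line block, a trended robust eBayes, each control alone and each array left out. An offset of 32 was added after seeing the data, because the planned offset came out low. The medians of lists against each control array of a line alone, and the counts of opposite and larger responses with signals raised and of genes too dim in one line to fall there, were added after seeing the results.

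The tests were tried on simulated data with 200 changed genes among 14220. For CDX against controls, 28.4% of genes changed by 1 on the log2 scale were recovered, 86.6% of those changed by 2 and 98.5% of those changed by 4. For CDX1 alone the shares were 4.48%, 76.1% and 97.0%, and for CDX2 alone 2.99%, 59.7% and 100%. For CDX2 against CDX1 they were 0%, 52.2% and 97.0%. For vector against uninfected they were 0%, 46.3% and 98.5%. For TMK1 against MKN7 they were 10.4%, 80.6% and 98.5%. For the interaction they were 0%, 10.4% and 83.3%. In the tests of CDX and vector the simulated changes were equal in both lines, with independent noise, so real arrays can recover fewer. With CDX1, RGS2 at 4.80 on the log2 scale did not pass (adjusted p = 0.218 by limma). A count of 0 therefore does not show that large changes are absent. A simulated list of 45 independent genes lowered by 1 on the log2 scale gave camera p = 8.64e-60 with the preset correlation and 1.6e-05 with an estimated one. Genes of real lists can move together, so this does not check the p-values of such lists. The plots were drawn with matplotlib 3.10.9 in Python 3.11.15.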

Results

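MKN7 and TMK1 are gastric cancer cell lines that lack CDX, per the series' design text. CDX1 and CDX2 are homeobox transcription factors of the intestinal epithelium, and intestinal metaplasia of the stomach expresses them. The design asks by what mechanism the factors stop growth, change cell shape and lead to cell death. Each line gave 4 arrays, from uninfected cells, cells with the empty vector, cells with CDX1 and cells with CDX2. Array medians of the intensity ran from 8.0 to 11.9, and 10.2% to 14.6% of the values on an array were below 1. Across genes, which are not independent replicates, arrays of the same line correlated at r = 0.935 to 0.978 and arrays of different lines at r = 0.756 to 0.807. The 3' to 5' signal ratio of GAPDH was 1.19 ± 0.06 (SD, n = 4) on the control arrays and 1.42 ± 0.037 (SD, n = 4) on the CDX arrays. The ratio of ACTB was 4.14 ± 1.4 (SD, n = 4) and 5.44 ± 1.96 (SD, n = 4). These SDs pool the lines, and the ACTB ratio was 2.9 to 4.12 on the MKN7 arrays and 4.78 to 7.79 on those of TMK1. The GAPDH ratio did not separate the lines, at 1.14 to 1.43 and 1.14 to 1.47. An exact two-sided permutation test within the lines gave p = 0.0556 for each ratio, the smallest p that its 36 arrangements allow. The only repeats of a transduction were the 2 cell lines, and no separate cultures are named, so p-values measure only the spread between these arrays.

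The probe sets for the introduced genes were dim. The CDX1 probe set read 4.5 on the CDX1 array of MKN7 and 3.8 on that of TMK1, within a range of 0.8 to 16.3 over the 8 arrays, and it exceeded the array median on 1 array. That 16.3 was on the CDX2 array of TMK1. In MKN7 its CDX2 array read 4.9. The brighter CDX2 probe set read 0.9 on the CDX2 array of MKN7 and 5.4 on that of TMK1, while the vector array of TMK1 read 22.3 and its CDX1 array 13.5. The other CDX2 probe set stayed between 0.5 and 6.3 and exceeded the array median on 0 arrays. Whether these probe sets lie inside the introduced sequence is not given in the sources used here, so they do not check the labels.

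CDX1 and CDX2 together were set against both controls to find what the factors changed in both lines. The tetraspanin TSPAN8 and the intestinal keratin KRT20 rose, together with RGS2, a regulator of G protein signalling, and ARL14, a small GTPase. The cytokine IL18, the epidermal transcription factor GRHL3 and the protease inhibitors PI3 and SPINK7 rose as well. IGFBP3, the collagen crosslinking enzymes LOXL2 and TGM2, complement C3 and the calgranulin S100A9 fell. TSPAN8 rose by 7.08 ± 0.68 (log2, SE), a 136-fold change with adjusted p = 0.016 by limma. Its signals of 13.6 and 6.3 on the uninfected and vector arrays of MKN7 stood against 5051 with CDX1 and 5450 with CDX2, and in TMK1 26.8 and 19.0 stood against 1213 and 788. KRT20 rose 33.1-fold (log2 5.05 ± 0.56, adjusted p = 0.0185), or 18.3-fold once dim signals were raised to the array median. RGS2 rose 31.6-fold (log2 4.98 ± 0.41, adjusted p = 0.00821) and ARL14 20-fold (log2 4.32 ± 0.30, adjusted p = 0.00488), the latter 14-fold with dim signals raised, since its TMK1 controls read 4.3 and 1.1. PI3 (log2 4.61), MARCHF3 (4.15), SPINK7 (4.07), RASSF6 (4.05), COBLL1 (3.39), IL18 (3.02), GRHL3 (2.96) and AHNAK2 (2.82) also rose, at adjusted p of 0.00488 to 0.0324. With dim signals raised, the folds of SPINK7, RASSF6 and GRHL3 were 10.5, 6.71 and 3.96 in place of 16.8, 16.5 and 7.76.

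Among the lower genes, IGFBP3 changed by -2.94 ± 0.44 on the log2 scale (adjusted p = 0.0324), with -1.85 in MKN7 and -4.03 in TMK1. It was -2.46 with dim signals raised, since the CDX arrays of TMK1 read 4.3 and 1.6. SLC7A2, a transporter of basic amino acids, changed by -2.73 ± 0.33 (adjusted p = 0.0252). S100A9 (-2.50), TNFRSF19 (-2.49), LOXL2 (-2.27), C3 (-2.23), the endothelin receptor EDNRB (-2.15), ARTN (-2.13), FCN3 (-2.07), TGM2 (-2.05), AQP3 (-1.80) and NNMT (-1.77) followed at adjusted p of 0.0185 to 0.0429. The fall of FCN3 rested on signals near background, since its log2 change was -0.08 with dim signals raised. ARTN fell 2.86-fold with dim signals raised, in place of 4.39-fold.

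In all, 135 genes were higher and 59 lower with CDX at an adjusted p under 0.05, of 14220 tested, and each of the 194 changed the same way in both lines. That was nearly set by the fit, which puts opposite responses of the lines into the spread, so such genes could hardly pass. Quantile normalization gave 104 higher and 75 lower, and centring each array on its median gave 108 higher and 127 lower, so the balance of directions depended on the scaling. Centring moved the median change of all genes from 0.06 to -0.05. The count also depended on the controls and on single arrays. With the vector as the only control 0 genes passed (smallest adjusted p 0.0589), and with uninfected cells alone 1. It was 5 without the CDX1 array of MKN7, 6 without its CDX2 array, 10 without its vector array and 105 without its uninfected array, and in TMK1 16 without CDX1, 24 without CDX2 and 82 without the uninfected array.

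**Figure D1:**
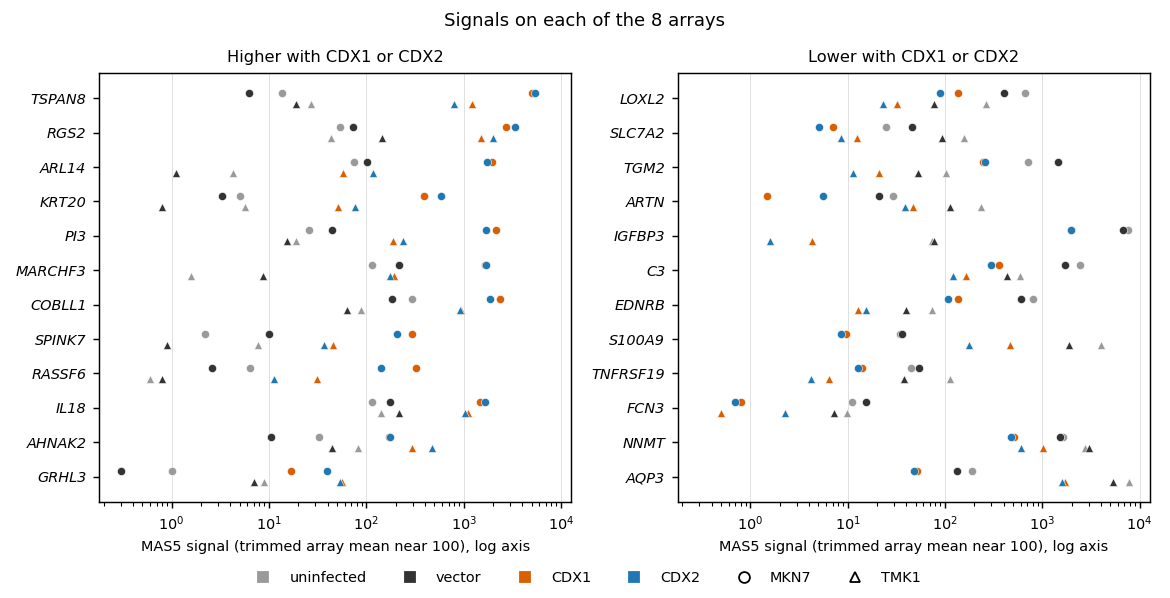
Intensity (log axis) of the 12 named higher and 12 named lower genes of the CDX comparison on each of the 8 arrays, coloured by transduction, with circles for MKN7 and triangles for TMK1. TSPAN8 reads 13.6 and 6.3 on the MKN7 controls and 5051 and 5450 on the MKN7 CDX arrays.

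Genes of mitosis and of DNA replication were lower with CDX. The kinetochore genes SPC25 and NDC80, the cytokinesis genes ANLN, PRC1 and KIF20A, cyclin A2 (CCNA2), DLGAP5 and CDCA3 fell in both lines. SPC25 changed by -1.59 ± 0.21 on the log2 scale (adjusted p = 0.0278), ANLN by -1.35 ± 0.18 (adjusted p = 0.0278) and CCNA2 by -1.48 ± 0.23 (adjusted p = 0.0343). DLGAP5 (-1.47), KIF20A (-1.39), PRC1 (-1.19), CDCA3 (-1.18) and NDC80 (-1.06) had adjusted p of 0.0401 to 0.0489. The median of the 45 mitotic and G2/M genes was -1.03, with -0.67 in MKN7 and -1.48 in TMK1, and 45 of 45 members were negative. In MKN7 it was -0.42 against uninfected cells alone and -0.90 against the vector alone, and in TMK1 -1.51 and -1.42. Camera gave adjusted p = 2.47e-26 for the list with a preset correlation and adjusted p = 0.551 with an estimated correlation, and fry gave adjusted p = 0.031. Of its members 8 fell over all genes and 40 when adjusted over the list alone. The 44 genes of G1/S and DNA replication had a median of -0.59 (camera adjusted p = 1.06e-12, adjusted p = 0.622 with an estimated correlation), and fry did not call them (adjusted p = 0.0631). In MKN7 their median was -0.17 against uninfected cells alone and -0.58 against the vector alone, and in TMK1 -0.55 and -0.87. Among them the nucleotide enzyme DUT fell by 0.93 ± 0.16 on the log2 scale (adjusted p = 0.0408), while E2F8 at -0.92 did not pass (adjusted p = 0.0589). Of this list 1 member fell over all genes, and 19 fell and 1 rose when adjusted over the list alone. GAPDH's 3' to 5' ratio was also 0.261 higher on the log2 scale on the CDX arrays. The 26 cell cycle inhibitors and senescence genes were not called (median 0.34, camera adjusted p = 0.342). Of these, IGFBP3 fell over all genes, while 7 rose and 1 fell when adjusted over the list alone. CCNG2 at 1.98 ± 0.44 (adjusted p = 0.0685) and CCND1 at 0.88 ± 0.19 (adjusted p = 0.0662) did not pass over all genes.

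Cell surface antigens of intestinal metaplasia, among them CEACAM adhesion molecules and claudins, were higher as a group. TSPAN8 led them, and CEACAM6 stood at 2.97 ± 0.61 on the log2 scale without passing (adjusted p = 0.0598). The 12 genes had a median of 0.92 (camera adjusted p = 0.000436, adjusted p = 0.253 with an estimated correlation), and fry gave adjusted p = 6e-06. Of the list 11 were higher in both lines, 1 rose over all genes and 8 rose when adjusted over the list alone. The list's median was smaller in MKN7, at 0.47 with CDX1 and 0.53 with CDX2, than in TMK1, at 1.29 and 0.93. The 27 enterocyte genes tested, of 51 with a probe set, had a median of 0.24 and were not called (camera adjusted p = 0.162). Among them KRT20 and the raft protein MALL (1.56 ± 0.28, adjusted p = 0.0479) rose over all genes, and 3 rose when adjusted over the list alone. The 13 intestinal transcription factors had a median of 0.51 (camera adjusted p = 0.0723, fry adjusted p = 0.0295). None of these 13 passed over all genes, and 5 rose and 1 fell when adjusted over the list alone. KLF4 stood at 1.84, FOXA1 at 1.33 and GATA6 at 1.32, with adjusted p over all genes of 0.0675 to 0.0777. The 14 goblet, Paneth and enteroendocrine genes had a median of 0.33 and a mean of 0.12 while the test pointed down (camera adjusted p = 0.957), and 0 were called over all genes or adjusted over the list alone. Of the 14 gastric epithelial genes (median 0.33, camera adjusted p = 0.721), gastrin (GAST) rose by 1.17 ± 0.21 (adjusted p = 0.0477). The trefoil factors TFF1 at -1.98 and TFF2 at -1.71 did not pass over all genes, and 1 gastric gene rose and 2 fell when adjusted over the list alone. The 15 stem cell and reprogramming genes had a median of 0.50 (camera adjusted p = 0.183). LGR5 at 2.40 and MYC at -0.72 did not pass, and 0 genes of the list passed over all genes, with 2 higher and 1 lower when adjusted over the list alone.

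The stress-induced transcription factor DDIT3 (CHOP), the executioner caspase CASP6, the autophagy gene MAP1LC3B and the chaperone gene DNAJB4 rose in both lines, while their lists as wholes were not called by camera. DDIT3 rose by 1.91 ± 0.34 on the log2 scale (adjusted p = 0.0448), CASP6 by 1.10 ± 0.16 (adjusted p = 0.0324), MAP1LC3B by 1.21 ± 0.21 (adjusted p = 0.0446) and DNAJB4 by 1.65 ± 0.29 (adjusted p = 0.0448). Under the alternative settings DDIT3 passed in 8 of 22 and CASP6 in 9 of 21. MAP1LC3B passed in 6 of 21 and DNAJB4 in 8 of 22. The 34 genes of the unfolded protein and integrated stress response had a median of 0.14 (camera adjusted p = 0.342), with 3 higher and 1 lower when adjusted over the list alone. CHAC1 stood at 1.23 and did not pass over all genes (adjusted p = 0.0542). The 37 apoptosis genes had a median of 0.08 (camera adjusted p = 0.693, fry adjusted p = 0.0113), with 1 higher and 1 lower when adjusted over the list alone. BIRC5, an apoptosis inhibitor that is also a mitotic gene, stood at -1.53 (adjusted p = 0.0635). The 25 p53 targets had a median of 0.18 (camera adjusted p = 0.162, fry adjusted p = 0.0358). None passed over all genes, and 1 rose when adjusted over the list alone. TP53I3 stood at 1.05 and GADD45A at 1.19 (adjusted p = 0.0589 and 0.109). The 32 lysosome and autophagy genes had a median of 0.19 (camera adjusted p = 0.162), with 4 higher and 2 lower when adjusted over the list alone, and the receptor SQSTM1 stood at 1.34 (adjusted p = 0.0542). The 16 heat shock genes had a median of 0.40 (camera adjusted p = 0.162), with 6 higher and 1 lower when adjusted over the list alone, and HSPA6 stood at 3.02 (adjusted p = 0.0607). In MKN7 the heat shock median was 0.36 against uninfected cells alone and 0.09 against the vector alone, and in TMK1 0.76 and 0.02.

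Genes of energy metabolism were lower over both lines, by less than the mitotic genes. The 39 genes of oxidative phosphorylation had a median of -0.30, with -0.11 in MKN7 and -0.51 in TMK1 (camera adjusted p = 5.19e-08, adjusted p = 0.622 with an estimated correlation). ATP5MC1 stood at -1.38 (adjusted p = 0.0587), and 0 members passed over all genes and 2 fell when adjusted over the list alone. The 33 genes of hypoxia and glycolysis had a median of -0.40 (camera adjusted p = 3.79e-05, adjusted p = 0.622 with an estimated correlation), with P4HA1 at -0.85, ENO1 at -0.62 and 0 members past the threshold either over all genes or adjusted over the list alone. The 32 ribosomal protein genes had a median of -0.16 (camera adjusted p = 0.000614, adjusted p = 0.737 with an estimated correlation), 0.00 in MKN7 and -0.34 in TMK1, and 0 members passed over all genes or adjusted over the list alone. Fry called none of these 3 lists (adjusted p = 0.11 for oxidative phosphorylation and 0.248 for each of the others). After quantile normalization the ribosomal list was no longer called. Against random lists of the same mean expression, oxidative phosphorylation stood in MKN7 at percentiles 7.83 with CDX1 and 14.6 with CDX2, and at 0 for both in TMK1. Against uninfected cells alone its median was 0.03 in MKN7 and -0.67 in TMK1, and against the vector alone -0.22 and -0.37. Hypoxia genes stood in MKN7 at percentiles 6.62 and 0.01, and at 0 for both in TMK1. In TMK1 the vector array alone had them at -0.73 against uninfected (percentile 0), so their CDX value there was -0.95 against uninfected and -0.31 against the vector. In MKN7 these values were -0.15 and -0.31, and the difference between the lines was not called (camera adjusted p = 0.0617). In TMK1 the ribosomal median stood at percentile 6.98 with CDX1 (-0.30, where random lists had -0.21) and 3.95 with CDX2 (-0.37 against -0.24). In MKN7 it stood at percentiles 66 and 91.1. The ribosomal change was thus little larger than that of other bright genes in TMK1 and absent in MKN7. The 26 genes of cholesterol and fatty acid synthesis (median 0.24, camera adjusted p = 0.235) were not called and had 0 members past the threshold over all genes or adjusted over the list alone. TM7SF2 stood at 1.01 (adjusted p = 0.0936). The 24 solute carrier and xenobiotic genes had a median of -0.04 and a mean of 0.04 (camera adjusted p = 0.629), with CYP2S1 at -1.26 (adjusted p = 0.0597), 0 calls over all genes and 2 lower when adjusted over the list alone.

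The desmosomal cadherin DSC2 rose by 2.24 ± 0.25 on the log2 scale (adjusted p = 0.0185), and the receptor kinase AXL fell by 1.66 ± 0.23 on that scale (adjusted p = 0.0297). AXL was near background in TMK1, where its signal was 8.8 on the controls. The 34 junction and polarity genes had a median of 0.23 (camera adjusted p = 0.0529), with 2 higher when adjusted over the list alone, and plakoglobin (JUP) stood at 1.08 and missed the threshold narrowly (adjusted p = 0.05). The 24 mesenchymal transition genes had a median of -0.04 (camera adjusted p = 0.28), and only AXL passed, over all genes as when adjusted over the list alone. Of the 18 Wnt targets (median 0.10, camera adjusted p = 0.595), TNFRSF19 fell, and 3 were higher and 1 lower when adjusted over the list alone. The 18 Notch genes had a median of 0.17 (camera adjusted p = 0.693), with HES1 at 1.55 (adjusted p = 0.0824). The 39 interferon response genes had a median of 0.19 (camera adjusted p = 0.647), with SAMD9 at 1.44 (adjusted p = 0.0957). The 13 histone genes had a median of 0.11 (camera adjusted p = 0.382), with H4C8 at 1.09 (adjusted p = 0.107). The Notch, interferon and histone lists had 0 members past the threshold over all genes or adjusted over the list alone. Of the 30 NF-kB and inflammatory genes (median -0.23, camera adjusted p = 0.162), S100A9 alone fell, over all genes and adjusted over the list alone, and NFKBIA stood at -0.86 (adjusted p = 0.0945). Of the markers of other cell types many had signals too low to be tested, or no probe set. The 6 fibroblast markers tested of 15 (median -0.11, camera adjusted p = 0.683) included DCN at 0.70, and the 8 leukocyte markers tested of 17 (median -0.10, camera adjusted p = 0.595) CD14 at -1.37. Neither had a member past the threshold over all genes or adjusted over the list alone. The 6 neural and embryonic kidney markers tested of 16 had a median of -0.05 and a mean of 0.50, with the test pointing up (camera adjusted p = 0.654). MAP2 stood at 2.66 (adjusted p = 0.0757), with 0 calls over all genes and 2 higher when adjusted over the list alone.

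**Figure D2:**
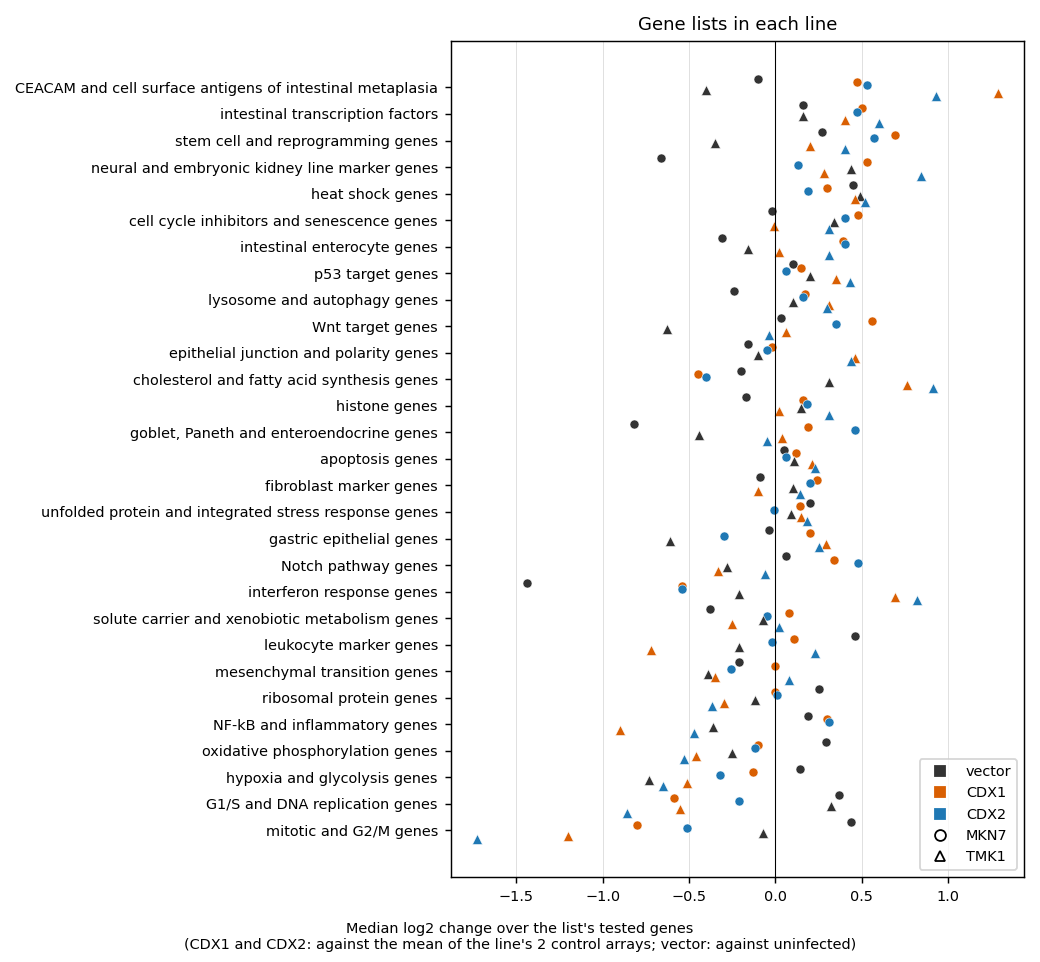
Median log2 change of each of the 29 lists in MKN7 (circles) and TMK1 (triangles), for CDX1 and CDX2 against the mean of the line's 2 control arrays and for vector against uninfected. The mitotic list is negative on the 4 CDX arrays and, for the vector arrays, 0.44 in MKN7 and -0.07 in TMK1.

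Set against the controls alone, each factor had TSPAN8, RGS2, KRT20 and ARL14 among its largest changes, and no gene passed. With CDX1, TSPAN8 stood at 7.21 ± 0.94 on the log2 scale, RGS2 at 4.80, KRT20 at 4.76 (3.90 with dim signals raised), RASSF6 at 4.67 (3.41 raised) and ARL14 at 4.11 (3.59 raised). On the lower side stood IGFBP5 at -2.93 ± 1.23, SLC7A2 at -2.53, FCN3 at -2.25 (-0.11 with dim signals raised), EDNRB at -2.13 and LOXL2 at -2. In MKN7 the value of IGFBP5 rested on the uninfected array (400.3), since the vector array read 3.0 and the CDX1 array 8.0. With CDX2, TSPAN8 stood at 6.96 ± 0.94, KRT20 at 5.34 (4.49 raised), RGS2 at 5.16, PI3 at 4.61 and ARL14 at 4.53 (4.02 raised). On the lower side stood SLC7A2 at -2.94, LOXL2 at -2.53, C3 at -2.42, NFATC1 at -2.12 and SRGN at -2.11, where NFATC1 was -0.33 with dim signals raised. By limma 0 genes passed for CDX1, with 1667 at an unadjusted p under 0.05 and a smallest adjusted p of 0.136. For CDX2 0 passed, with 1882 at an unadjusted p under 0.05 and a smallest adjusted p of 0.142. A trended and robust eBayes called 9 genes for CDX1 and 15 for CDX2. The mitotic list had a median of -1.04 with CDX1 (camera adjusted p = 2.39e-21, adjusted p = 0.627 with an estimated correlation) and -1.03 with CDX2 (camera adjusted p = 2.27e-24, adjusted p = 0.708 with an estimated correlation). Adjusted over the list alone, 16 mitotic genes fell with CDX1 and 22 with CDX2, against 0 over all genes. The G1/S list, at -0.59 and -0.67, and the CEACAM list, at 0.95 and 0.89, were called for both factors. For G1/S, camera gave adjusted p = 5.93e-11 with CDX1 (adjusted p = 0.627 with an estimated correlation) and 6e-13 with CDX2 (adjusted p = 0.708 with an estimated correlation). For CEACAM it gave adjusted p = 0.00104 with CDX1 (adjusted p = 0.627 with an estimated correlation) and 0.00297 with CDX2 (adjusted p = 0.708 with an estimated correlation). Fry called the CEACAM list for both factors (adjusted p = 0.00547 and 0.00394). It called neither the mitotic nor the G1/S list, at adjusted p = 0.204 for each with CDX1 and 0.184 for each with CDX2. Oxidative phosphorylation stood at -0.30 with CDX1 and -0.35 with CDX2, hypoxia and glycolysis at -0.37 and -0.42, and the ribosomal list at -0.16 and -0.18, all called by camera and none by fry or with an estimated correlation. The hypoxia list lost its call for CDX1 without the uninfected or the CDX1 array of TMK1. The ribosomal list lost it for either factor without the uninfected array or that factor's array of TMK1, and after quantile normalization.

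The factors were then set against each other, to ask where CDX2 acts differently from CDX1. No gene separated them. SPATA19 at 2.57 ± 0.46, PAX5 at 2.06, KLK13 at 2.02, C3P1 at 1.91 and LOC285819 at 1.87 were higher with CDX2. PKHD1L1 at -2.74 ± 0.96, HOXC13 at -1.96 ± 0.38, CRYAA at -1.69, STK32A at -1.62 and SLC25A47 at -1.61 were higher with CDX1, as values that did not pass (adjusted p = 1 for each). With dim signals raised, SPATA19 was 0.32, PAX5 0.31, KLK13 0.21, C3P1 0.10, LOC285819 0.19, PKHD1L1 -1.12, HOXC13 -1.23, CRYAA -0.19, STK32A -0.10 and SLC25A47 0.01. By limma 0 genes passed, with 230 at an unadjusted p under 0.05 where chance gives 711. The spread of this fit includes differences of the CDX response between the lines, which widens it. A count under that of chance is therefore no measure of likeness. At 2-fold with no test, CDX2 against CDX1 gave 916 genes in MKN7 and 1261 in TMK1. The 95% interval of the difference had a median half-width of 0.82 on the log2 scale and lay within 1 of 0 for 7009 genes (49.3%). Of the 194 genes called for CDX, 102 had such an interval, and over the 194 the largest absolute difference was 1.25. These 194 were called with the factors pooled, where a difference between the factors adds to the spread. Small differences among them were therefore favoured by the selection. Camera called 0 lists, as did fry and camera with an estimated correlation. The mitotic list had a median of -0.07 (camera adjusted p = 0.524), but 0.32 in MKN7, where 4 of 45 members were negative, and -0.42 in TMK1, where 42 were. The pooled test does not see such opposite differences between the factors. Without the CDX2 array of MKN7 camera called 7, without its CDX1 array 2, and in TMK1 6 without CDX1 and 5 without CDX2. Across genes, which are not independent replicates, the CDX1 and CDX2 changes correlated at r = 0.786 in MKN7 and 0.728 in TMK1, against 0.331 and 0.334 for simulated unchanged groups that share the controls. With the controls split, r was 0.531 and 0.541 in MKN7 and 0.417 and 0.433 in TMK1. The covariance was 0.496 in MKN7 and 0.45 in TMK1, which exceeded the simulated covariances of 0.0974 and 0.0986 by 0.399 and 0.351.

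The vector was set against uninfected cells to see what differed between the 2 controls, without CDX. No day is given for the uninfected cells, so infection and selection cannot be told apart from time in culture. List-level differences lay in interferon, heat shock and replication genes, and no gene passed. CLEC7A stood at -2.59 ± 0.51, PSLNR at -2.58 ± 0.63, PLCB2 at -2.87 ± 0.54, SHISA4 at -2.35 and OR13C4 at -2.22 on the lower side. HSPA6 at 1.70 ± 0.70, COL23A1 at 1.70, ASPG at 1.68, GUCY2C at 1.72 and ANKRD26P3 at 2.06 stood on the higher side, and with dim signals raised GUCY2C was -0.09, COL23A1 -0.09, ANKRD26P3 0, ASPG 0.53 and HSPA6 0.93. Raised in that way, PLCB2 was -1.65, PSLNR -1.77, SHISA4 -1.25 and OR13C4 -1. Each had an adjusted p of 0.798. By limma 0 genes passed, with 874 at an unadjusted p under 0.05 where chance gives 711. The interferon list had a median of -0.80 (camera adjusted p = 2.94e-05, adjusted p = 0.921 with an estimated correlation), -1.44 in MKN7 and -0.21 in TMK1. IFITM1 stood at -2.37 and OAS1 at -2.06. Without the uninfected array of MKN7 the list's median was 0.12 and it was not called. The G1/S list was 0.40 (camera adjusted p = 1.16e-07, adjusted p = 0.921 with an estimated correlation) and 42 of its 44 members were positive. The heat shock list was 0.40 (camera adjusted p = 5.13e-05, adjusted p = 0.476 with an estimated correlation), with HMOX1 at 1.48. The mitotic list was 0.18 (camera adjusted p = 0.00256, adjusted p = 0.921 with an estimated correlation), 0.44 in MKN7 and -0.07 in TMK1. It was not called after quantile normalization, nor without the uninfected array of MKN7 (median -0.27) or the vector array of TMK1 (median 0.02). In these 4 lists 0 members passed over all genes or adjusted over the list alone, and fry called 0 lists.

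TMK1 and MKN7 differed widely whatever they carried. TMK1 was higher in S100P, FABP5, NQO1, the antigens CTAG2 and MAGEA4, fibrinogen gamma (FGG) and BMP2. MKN7 was higher in fibronectin (FN1), the Wnt inhibitor DKK1, placental alkaline phosphatase (ALPP), calbindin (CALB1), AXL, and the matrix genes COL12A1 and VCAN. S100P differed by 10.71 ± 0.24 on the log2 scale, 1670-fold or 769-fold with dim signals raised, and FN1 by -10.57 ± 0.18, 1520-fold or 494-fold with dim signals raised. FABP5 (10.17), NQO1 (9.61), GTSF1 (9.52), CES1 (9.44), IFI27 (9.40), CPE (9.20), CTAG2 (9.18), FGG (8.74), BMP2 (8.63), MAGEA4 (8.29) and CRIP1 (8.26) were the other named genes higher in TMK1. DKK1 (-9.69), ALPP (-9.39), CALB1 (-9.25), UCA1 (-8.87), COL12A1 (-8.79), AXL (-8.78), PDGFC (-8.69), ALCAM (-8.62), VCAN (-8.46), LARP6 (-8.44) and INHBA (-8.43) were higher in MKN7. Many of these sizes rest on signals near background in the other line. With dim signals raised the named values ran from 7.52 for BMP2 to 9.59 for S100P, and from -7.36 for VCAN to -8.95 for FN1. Limma called 2589 genes higher and 3384 lower in TMK1, with adjusted p from 4.67e-05 upwards. Quantile normalization gave 2969 higher and 2937 lower, and centring gave 3415 higher and 2727 lower while moving the median of all genes from -0.10 to 0.09. Under quantile normalization that median was 0.01.

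The last test asked where the lines answered CDX differently. Its only repeats within a line were CDX1 with CDX2 and uninfected with vector, which are different treatments and not replicate arrays. The kinase gene DCLK1, the collagenase MMP1, the stromelysin MMP10 and the keratin-associated gene KRTAP3-1 had much higher values with CDX in MKN7 than in TMK1. CEACAM1, CEACAM5, CEACAM7 and the ferroxidase HEPH had the higher response in TMK1, and the growth factor TGFB2 went opposite ways. The connexin gene GJA5 was lower with CDX in MKN7 and dim in TMK1. DCLK1 changed by 7.46 in MKN7 and -0.66 in TMK1, a difference of -8.12 ± 0.64 on the log2 scale (adjusted p = 0.0181). KRTAP3-1 changed by 6.78 and -0.01 (adjusted p = 0.0056), and MMP1 by 6.62 and -0.11 (adjusted p = 0.0181). GEM changed by 4.20 and -2, CLCA2 by 3.05 and -3.06, MMP10 by 4.43 and -1.53, and RGCC by 2.12 and -2.65. GDA (-5.60), SCN9A (-4.93), IL33 (-4.53), RAI2 (-4.49) and AADACP1 (-4.33) completed the named genes with the lower TMK1 response. Several of these sizes rested on dim signals. With those raised the difference was -2.32 for MMP10 in place of -5.96, -2.19 for AADACP1, -2.79 for RAI2, -3.95 for IL33, -3.99 for SCN9A and -4.04 for RGCC. It was -4.53 for CLCA2 in place of -6.11, -5.12 for KRTAP3-1 in place of -6.79, -7.08 for DCLK1 and 4.07 for GJA5 in place of 6.06. In the other direction GJA5 changed by -5.00 in MKN7 and 1.06 in TMK1 (adjusted p = 0.0449), where only its CDX1 array, at 20.5, exceeded the array median. TGFB2 changed by -2.40 and 2.08 (adjusted p = 0.0181) and HEPH by 0.18 and 5.16 (adjusted p = 0.0254). CEACAM1 changed by 0.81 and 5.38, CEACAM7 by 0.37 and 4.81 and CEACAM5 by 0.32 and 3.70. The CEACAM1 probe set is of a kind that can cross-hybridise to related genes. HSD3B1 (4.24), KLK5 (4.06), ANKFN1 (3.93), GBP3 (3.66), MATN2 (3.52) and CRYBG1 (3.40) were the others. In all, 29 genes had the higher and 51 the lower response in TMK1, 60 of the 80 had the larger response in MKN7, and 58 had opposite signs in the lines, 15 of them with a change of at least 1 on the log2 scale in each line. With dim signals raised these were 46 and 9. The count was 0 without the CDX1 or the CDX2 array of MKN7, 24 without its vector array and 5 without its uninfected array. In TMK1 it was 1 without CDX1, 2 without CDX2 and 6 without the uninfected array.

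**Figure D3:**
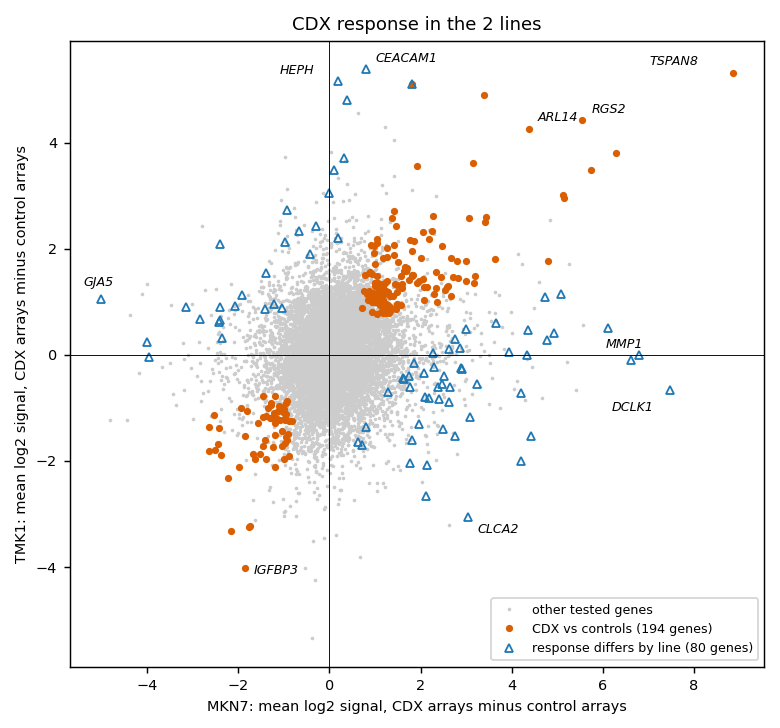
Log2 change with CDX in MKN7 (x axis) and TMK1 (y axis) for each tested gene, with the 194 genes called for CDX in orange and the 80 genes whose response differed between the lines as blue triangles. DCLK1, at 7.46 and -0.66, lies farthest from equal responses among the 80.

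By camera with the preset correlation, but for none with an estimated one, 8 lists also differed between the lines. Cholesterol and fatty acid synthesis was lower with CDX in MKN7 (median -0.44) and higher in TMK1 (0.83), as were interferon response genes (-0.63 and 0.79), while inflammatory and Notch genes had the opposite order. The cholesterol list differed by a median of 1.11 (camera adjusted p = 5.41e-10, adjusted p = 0.567 with an estimated correlation), with 15 of 26 members past the threshold when adjusted over the list alone and 0 over all genes. DHCR7 at 2.61, SREBF2 at 2.37 and FASN at 2.10 did not pass over all genes. The interferon list differed by 1.38 (camera adjusted p = 1.21e-07, adjusted p = 0.755 with an estimated correlation), with 8 members adjusted over the list alone and 0 over all genes, and IFIT1 stood at 5.21. The lower interferon value in MKN7 rested on its uninfected array. Its CDX arrays stood at -1.32 against uninfected but 0.11 against the vector, and those of TMK1 at 0.63 and 0.87. The cholesterol list stood in MKN7 at -0.71 against uninfected and -0.17 against the vector, and in TMK1 at 0.97 and 0.75. The NF-kB list differed by -0.71 (camera adjusted p = 0.000152, adjusted p = 0.567 with an estimated correlation), and IL1A passed at -2.99 ± 0.42 (adjusted p = 0.0449) with 9 members adjusted over the list alone. The Notch list differed by -1.36 (camera adjusted p = 0.0141, adjusted p = 0.567 with an estimated correlation), and HEY1 passed at -3.80 ± 0.50 (adjusted p = 0.0396) with 6 members adjusted over the list alone. The mitotic list differed by -0.82 (camera adjusted p = 7.66e-06, adjusted p = 0.755 with an estimated correlation), oxidative phosphorylation by -0.38 (camera adjusted p = 0.000335, adjusted p = 0.755 with an estimated correlation), the ribosomal list by -0.35 (camera adjusted p = 0.00126, adjusted p = 0.806 with an estimated correlation) and the junction list by 0.41 (camera adjusted p = 0.0108, adjusted p = 0.567 with an estimated correlation). In these 4 lists 0 members passed over all genes or adjusted over the list alone. The differences also depended on the control. Against uninfected cells alone and against the vector alone they were -1.09 and -0.52 for the mitotic list, -0.69 and -0.15 for oxidative phosphorylation and -0.52 and -0.17 for the ribosomal list. For the junction list they were 0.45 and 0.42, for the Notch list -0.91 and -0.54 and for the NF-kB list -1.04 and -0.67. The junction and ribosomal lists were not called without the uninfected array of MKN7, nor the ribosomal list after quantile normalization. Fry called 1 list, the CEACAM genes (adjusted p = 0.0181), which camera did not (median 0.17, camera adjusted p = 0.453).

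Within a single line no test was run, and each CDX array was set against both controls at 2-fold. In MKN7, UGT2B17 read 409.5 with CDX1 against 3.0 and 2.5 on the controls, and the secreted protein CRISP3 read 42.5 with CDX2 against 4605 and 1204. In TMK1, KRT14 read 252.7 with CDX2 against 0.3 and 4.8, and the chemokine CXCL8 read 27.9 with CDX1 against 350.2 and 1250. In MKN7 787 genes were higher and 469 lower with CDX1, and 768 and 448 with CDX2. In TMK1 530 were higher and 652 lower with CDX1, and 698 and 696 with CDX2. For scale, vector against uninfected alone gave 1452 genes in MKN7 and 2101 in TMK1. The vector array against both the uninfected and the CDX1 array, a count of the same form, gave 577 and 636. The uninfected array against the vector and CDX1 arrays gave 559 and 1088. With CDX1, 103 of the higher genes were shared between the lines where independent lists would share 29.3, and 53 of the lower ones against 21.5. With CDX2 the numbers were 99 against 37.7 and 46 against 21.9. The independent numbers take every gene as equally likely to pass 2-fold. Ratios of dim genes are less stable in either line, so an excess alone does not show a shared response. No such overlap was computed for vector against uninfected. Across genes, which are not independent replicates, the CDX change correlated between the lines at r = 0.18, and at r = 0.346 over the 5688 brighter genes, against 0.109 and 0.209 for vector minus uninfected.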

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

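The tests of RNA quality, of one line having received or made less CDX and of lists against each control alone, and the counts of larger responses with signals raised and of genes unable to fall, were chosen only after the results were seen, and the bound for differences between the factors was revised then.

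The response to CDX differed between the lines for 80 genes by limma's interaction test, given as the change in TMK1 minus that in MKN7 on the log2 scale. The response was higher in TMK1 for GJA5 (6.06), HEPH (4.98), CEACAM1 (4.57), TGFB2 (4.48), CEACAM7 (4.43), HSD3B1 (4.24), KLK5 (4.06), ANKFN1 (3.93), GBP3 (3.66), MATN2 (3.52), CRYBG1 (3.40) and CEACAM5 (3.38). It was lower in TMK1 for DCLK1 (-8.12), KRTAP3-1 (-6.79), MMP1 (-6.72), GEM (-6.20), CLCA2 (-6.11), MMP10 (-5.96), GDA (-5.60), SCN9A (-4.93), RGCC (-4.78), IL33 (-4.53), RAI2 (-4.49) and AADACP1 (-4.33). By camera with the preset correlation, and by none with an estimated correlation, 8 lists differed between the lines. Their median differences were 1.38 for interferon response, 1.11 for cholesterol and fatty acid synthesis, 0.41 for junction and polarity, -0.35 for ribosomal proteins, -0.38 for oxidative phosphorylation, -0.71 for NF-kB and inflammation, -0.82 for mitosis and G2/M and -1.36 for the Notch pathway.

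Once signals were raised to the array median, 92.5% of the 80 genes (74) kept their sign and a difference of at least 1 on the log2 scale. That says nothing about 9 genes, GJA5, HSD3B1 and ANKFN1 among them, whose larger response was a fall while the controls of the other line were dim. Of the other 71 genes 66 (93%) kept it. The bar was low, since the interaction test recovered 0% of simulated differences of 1 and 10.4% of those of 2. Called genes therefore had large differences and could lose much of them and still count, as MMP10 did from -5.96 to -2.32. GJA5 shrank to 4.07. The values show that most differences did not vanish with dim signals raised, and not how much of each rested on low signals. A weaker dose of CDX in one line, as the sole cause, would give nearly all genes their larger response in the other line. Of the 80, 25% (20) had it in TMK1 and 60 in MKN7, and with dim signals raised 26.2% (21) had it in TMK1. That speaks only against dose as the sole cause, since a weaker dose in TMK1 would also give most genes their larger response in MKN7. Of the 194 genes called for CDX, 108 had it in MKN7. The dose was not measured, since the CDX probe sets were dim. The differences of lists depended on the control, and that of interferon was 1.95 against uninfected cells alone and 0.76 against the vector alone, since the CDX arrays of MKN7 stood at -1.32 against the first and 0.11 against the second. The same arrays gave the pattern and these tests, and the count fell to 0 without the CDX1 or the CDX2 array of MKN7, so a difference between the lines is a hypothesis, and no biological explanation was tested.

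Mitotic genes were lower on the CDX arrays, by a median of -1.03, and the scaling of the arrays does not account for it, since the median was -1.02 after quantile normalization and -1.14 after centring. RNA quality stays open. The 3' to 5' ratio, measured on control probe sets outside the gene tests, was 0.261 higher on the log2 scale on the CDX arrays for GAPDH and 0.385 higher for ACTB. The vector arrays had 44.9% of the CDX rise in the GAPDH ratio in MKN7 and 30.5% in TMK1, which predicts mitotic changes of -0.19 and -0.46 for vector against uninfected, and the values were 0.44 and -0.07 (0.18 over both lines). MKN7 goes against RNA quality as the cause while TMK1 keeps the predicted sign, so RNA quality and CDX cannot be told apart here. Growth arrest by CDX was not tested.

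The responses to CDX1 and CDX2 were alike across genes. Shared control arrays alone would bring the correlation under 0.25 once the controls were split, and the lowest of the split correlations was 0.417. Differences between the factors that both lines share would make the CDX2 minus CDX1 change correlate between the lines, and it correlated at -0.0823 over all genes and -0.296 over brighter genes. The bound set beforehand, r at or below 0.1, was wrong for differences in one line or opposite in the lines, and the mitotic median of CDX2 minus CDX1 was 0.32 in MKN7 and -0.42 in TMK1. With 1 array per factor and line, a difference between the factors and one between single arrays cannot be told apart there.

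Of the 34 splits of the 8 arrays into 4 and 4 that could be fitted with the line as a block, 1 called as many genes as CDX against controls, the real one with 194, and the highest of the others called 1. The unbalanced ones among these exchange arrays between the lines, which the design does not. Every split but the real one, balanced or not, leaves at least part of the CDX change in the residual spread. The low counts of the others were therefore largely set in advance. Of the 18 splits balanced over the lines, 1 called as many, again the real one, with 1 gene for the highest of the others, and 18 splits are too few for a share under 0.05. For TMK1 against MKN7, 1 of 32 splits called as many genes, the real one with 5973, and the highest of the others called 0. Only 8 of these keep 1 array of each transduction on either side, too few for a share under 0.05, and every split but the real one leaves at least part of the difference between the lines in the residual spread.

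When every probe set was tested on its own, 17 of the 178 called for CDX against controls had no single gene symbol, 13 higher and 4 lower, out of 5656 such probe sets among 32824. They stand outside the tests by gene.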

How the results depend on the processing

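The offset of 32 was chosen only after the data were seen, and the other settings before. Among the values for whole comparisons under these settings, 159 stayed the same, 57 moved, 12 gained and 11 lost a call, and among those for single genes and lists 5658 stayed the same, 739 lost and 256 gained a call and 11 reversed. The cause was not tested for the changes below unless one is given.

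For CDX against controls, the main setting called 194 genes, and the alternatives 107 with no offset, 523 with the offset at the 50th percentile and 802 with an offset of 32. They called 30 with no filter, where 19775 genes shared the adjustment, and 644 with the stricter filter, 103 with the mean of a gene's probe sets, 125 without _x_at and _s_at probe sets and 843 with a trended robust eBayes. Of the 194, 190 were called again with the 50th percentile, 171 with an offset of 32 and 186 with the trend. With the vector as the only control, on 6 arrays, 0 genes passed by limma (smallest adjusted p 0.0589), and with uninfected cells 1. Without the line as a replicate block 3 passed, since the difference between the lines then entered the spread. Leaving out one array at a time gave 5 to 147. Single genes differed in how often they passed. RGS2 passed in 21 of 22 settings, IL18 in 19 and TSPAN8 in 18. Of the called mitotic genes, ANLN passed in 13 of 22, SPC25 in 12, CCNA2 in 11, DLGAP5 in 9, CDCA3 and NDC80 in 7 each and KIF20A in 6. PRC1 passed in 7 of 21 and the replication gene DUT in 7 of 22. S100A9 passed in 7, MALL in 5 and GAST in 4 of 22, and LOXL2 in 7 of 21.

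By the mean of a gene's probe sets, RPS12 was 0.105, NDUFS7 0.064, DCN -0.041 and FBLN1 0.558 for CDX against controls and STK32A 0.078 for CDX2 against CDX1, each reversed. HSPB8 reversed to -0.666 without _x_at and _s_at probe sets and THY1 to -0.058 with the vector as the only control. FBLN1 ran from -0.639 to 1.3 with single arrays left out. None of these genes had passed.

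For CDX1 against controls 5 genes passed with the 50th percentile, 1 with the stricter filter, 9 with the trend and 6 with an offset of 32, and for CDX2 the numbers were 6, 6, 15 and 10. TMK1 against MKN7 called 11760 probe sets when every probe set was tested on its own. No setting called a gene for CDX2 against CDX1 or for vector against uninfected.

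The interaction called 80 genes, against 27 with no offset, 450 with the 50th percentile, 721 with an offset of 32, 5 with no filter, 224 with the stricter filter, 27 for every probe set, 15 without _x_at and _s_at probe sets and 470 with the trend. With CDX1 only or CDX2 only against both controls, on 6 arrays, limma called 0. Single arrays left out gave 0 to 80. The line is part of this model, so there was no fit without it.

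Camera with an estimated correlation called 0 lists for CDX, for CDX1, for CDX2, for vector against uninfected and for the interaction. Fry called 3 for CDX1, 2 for CDX2, 0 for vector against uninfected and 1 for the interaction. With single arrays left out, camera called 6 to 10 lists for CDX1, 0 to 7 for CDX2 against CDX1 and 4 to 7 for vector against uninfected, where the mitotic median ran from -0.268 to 0.647 and the interferon median from -1.678 to 0.124.

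Within a line, the vector as the only control gave 2449 genes for CDX1 and 2437 for CDX2 in MKN7 and 2192 and 2546 in TMK1, and uninfected cells as the only control gave 2292, 2263, 3220 and 3414, since a single control is easier to pass. At 3-fold the counts were 475, 497, 379 and 451, and with the 50th percentile 795, 797, 559 and 754. Splitting the controls lowered the correlation of CDX1 and CDX2 to 0.531 and 0.541 in MKN7 and to 0.417 and 0.433 in TMK1. Signal over background limits the changes of dim genes, for which each added offset shrinks the fold.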

Other observations

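Several genes outside the comparisons above changed within a single line, as values without a test. In MKN7, the bladder plaque gene UPK1B read 7.1 with CDX1 against 162.0 and 177.5 on the controls, the potassium channel KCNJ15 8.9 against 334.2 and 111.6, and GRAMD2A 1.6 with CDX2 against 159.9 and 48.1. In TMK1, the ubiquitin ligase gene TRIM36 read 110.0 with CDX1 against 0.8 and 1.5, and the glycosyltransferase GALNT16 2.2 against 83.8 and 61.0. Psoriasin (S100A7), at 0.8 against 466.8 and 55.6, and the calgranulin S100A8, at 64.2 against 2316 and 629.9, were lower with CDX2 in TMK1.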
